A study of Homo sapiens with 11 samples.

How the data were processed

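Expression was measured by RNA sequencing of MCF7L cells and a tamoxifen-resistant derivative after siRNA transfection, and of MCF7L cells with doxycycline-inducible FOXA1. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and libraries were made with a TruSeq RNA kit. The submitters' processing notes list hg19 as the build and bcl2fastq 1.8.3, Bowtie and Cufflinks as tools, without their role, order or further versions. The strand setting, the annotation and the treatment of reads that fit several genes are not given in the sources used here.

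The values are RPKM, per the file headers, computed by the authors before deposit as reads scaled by gene-model length and library size. Each of the 9 files held 23160 rows in 1 gene order, with symbols and no coordinates. The row without a gene name, 28 rows whose symbols had become dates and 4 rows with a repeated symbol were looked at. The unnamed row and the repeated symbols were left out, which left 23155 genes. Of these, 22382 symbols matched a RefSeq symbol or synonym. No coordinate is printed because the annotation used here, GENCODE 29 on GRCh38, is of another build than the files. Where the labels listed 2 samples of a siFOXA1 group, both named 1 file, and how that file was made from them is not stated.

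Groups were taken from the labels and files from the deposited assignment of each file to its sample. The file assigned to the parental siFOXA1 group has TR in its name, as has the file of the TamR siFOXA1 group, and the assignment was kept. Values were compared between files before use. Pairs of files with identical values were analysed under both labels, as the design fixed before the data were examined required, and only distinct profiles entered the mean used to filter genes.

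Low RPKM values were tested for whole reads. For each gene with a value above 0 in at least 4 of the 7 distinct profiles, 1 gene-model length was sought that made its values in all profiles whole reads within 0.05 reads, which succeeded for 15394 of 17042 genes (90.3%). The denominators found in this way were whole numbers of M reads (M for mega), between 11 and 63, so a rounding of the denominators can shift a whole library by up to 4.55% (TamR siControl) or less. Among 1611 genes with a single GENCODE transcript, the recovered length over that transcript's length had a median of 1.00. Genes without a recovered length were given the longest GENCODE transcript, which applies to FOXA1 and ESR1, so their read numbers are approximate. On simulated reads, 99.5% of 2911 solved lengths lay within 1% of the length drawn. The reads were used only for depth and for 95% counting intervals of ratios (Clopper-Pearson on the share of reads) or of single values (exact Poisson). These cover counting error and not variation between cultures or libraries. A bound against a profile without reads used a floor of 3 reads in that profile.

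Differences were computed as log2((a + 1)/(b + 1)) of RPKM with a pseudocount of 1, which understates differences of low genes, and folds are plain RPKM ratios. Genes with a mean of at least 1 RPKM over the 7 distinct profiles (12483) were counted as higher or lower at 2-fold on the log2 scale. No test was run because each group had 1 profile. In simulated data for the library labelled siFOXA1 against TamR siControl (12422 genes with a length), 99.5% of 200 genes raised 4-fold passed this rule, and on average 31.1 unchanged genes passed too. The simulation assumed a dispersion (variation beyond counting error) of 0.01, which could not be measured with 1 profile per group. Variation between cultures or libraries beyond this value is not covered, so 31.1 is not an estimate of false calls in the real data. Gene lists (27, of which 22 had at least 5 measured members) were fixed before the data were examined. A list's median difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries.

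Correlations across genes were computed without p-values. Where 2 differences shared a library, r and covariance were also computed on 20 simulated sets of unchanged profiles with the same depths and an assumed dispersion of 0.01. Genes were named by a rule fixed before the data were examined: the targeted gene, the 10 highest and 10 lowest genes with at least 5 RPKM in the higher profile (without pseudogenes, small RNAs and repeated symbols), up to 4 members of each list with the largest difference, and 10 genes fixed by name (FOXA1, ESR1, IL8, PGR, TFF1, GREB1, GATA3, XBP1, EGFR and ERBB2). The relation to gene-model length used 12422 genes in quintiles of length.

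Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 RPKM, upper-quartile scaling, setting the median difference to 0, leaving out small RNA and ribosomal protein genes, and, for the counts and targets of the library labelled siFOXA1 and of TamR siER and for 1 correlation, TamR siIL8 in place of TamR siControl. The same replacement for list medians, TamR siER in place of TamR siControl, and setting the median of each length quintile to 0 were chosen after seeing the data. A count was taken as unchanged within 1.5-fold, a target within its counting interval, a correlation within 0.1 and a list median within 0.58 on the log2 scale. Computations used Python 3.11.15 with numpy, pandas, scipy and matplotlib.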

Results

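RNA was sequenced from MCF7L cells, a line of the estrogen receptor-positive MCF-7 breast cancer cells, and from a tamoxifen-resistant derivative (TamR). The labels describe 11 samples in 9 groups. TamR cells were transfected with a control siRNA or with siRNAs against FOXA1, the estrogen receptor or IL8, and parental cells with a control siRNA or siRNAs against FOXA1 or the estrogen receptor. A further pair of groups carried FOXA1 under a doxycycline-inducible promoter, without and with doxycycline. Each group had 1 deposited expression profile, also where 2 samples were labelled, so no difference has a replicate check and no p-value is given. Values are RPKM per gene symbol, and 12483 of 23155 genes had a mean of at least 1 RPKM. The steps between low values corresponded to denominators, in M reads, of 11 in the TamR siControl library, 24 in parental siControl, 36 in TamR siER, 34 in TamR siIL8, 63 in the library labelled siFOXA1, and 26 and 19 in those labelled without and with doxycycline.

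The 9 files held 7 distinct profiles. The files labelled TamR siFOXA1 and parental siFOXA1 had identical values, 17970 of them above 0, and so did the files labelled TamR siIL8 and parental siER, with 17034 above 0. Every other pair of files shared at most 67 identical values above 0. The 2 shared profiles were placed on 226 genes that differed at least 8-fold between the TamR siControl library, set to 1, and the parental siControl library, set to 0. Their median positions were 0.94 and 0.95, against 0.98 for TamR siER and 0.20 and 0.06 for the libraries labelled without and with doxycycline. Comparisons under the parental siFOXA1 and siER labels are therefore given with this limit, and neither library was moved to another group.

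FOXA1, a pioneer factor that opens chromatin for the estrogen receptor, was not lower in the library labelled siFOXA1. It measured 261 RPKM there, against 202 in TamR siControl (ratio 1.29, 95% counting interval 1.26 to 1.33) and 86.8 in parental siControl. In the inducible pair FOXA1 was 780 RPKM in the library labelled without doxycycline and 121 in the library labelled with it, 6.44-fold lower (6.28 to 6.61). Both results go against the labels. ESR1, which encodes the estrogen receptor, was 18.9 RPKM in TamR siER against 30.9 in TamR siControl, a ratio of 0.61 (0.579 to 0.642), and it was lower still, at 15.5 RPKM, in TamR siIL8 (ratio 0.501, 0.475 to 0.529). It lies in the longest quintile of gene-model length, whose median log2 difference was -0.59 in TamR siIL8 and 0.13 in TamR siER. The lower ESR1 value in TamR siIL8 is therefore not separate from that library's length trend. This profile also carries the parental siER label, so whether it came from an siIL8 or an siER transfection stays open. IL8, a chemokine gene, was 7.66 RPKM in TamR siIL8 against 105 in TamR siControl, 13.8-fold lower (12.4 to 15.3), but it was also 4.0 RPKM in the library labelled siFOXA1 and 26.6 in TamR siER. In parental siControl IL8 measured 0.0733 RPKM.

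**Figure D1:**
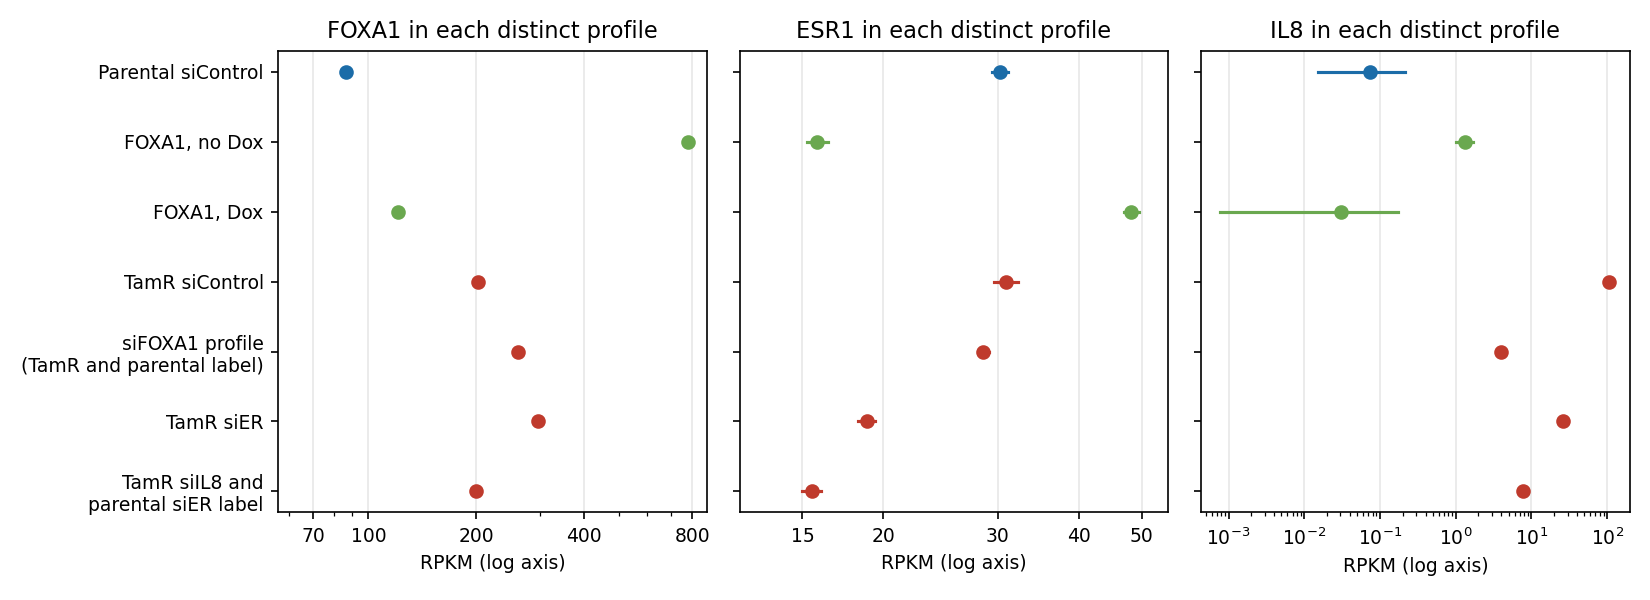
RPKM of FOXA1, ESR1 and IL8 (log axes) in the 7 distinct profiles, with exact 95% Poisson counting intervals as bars, many narrower than the point; blue marks the parental library, green the inducible pair and red the profiles that carry a TamR label. FOXA1 was highest, at 780 RPKM, in the library labelled without doxycycline, and IL8 was highest, at 105 RPKM, in TamR siControl.

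How the resistant line differs from its parent was addressed by the TamR and parental siControl libraries. Interferon-stimulated genes were lower in TamR: 35 of 37 measured members were at least 2-fold lower and 1 was higher, with a median log2 difference of -4.45, below all 10000 expression-matched random lists. IFI27 measured 0.279 RPKM in TamR and 1348 in parental cells, IFI6 1.48 and 760, IFITM3 5.04 and 1277, and BST2, which encodes tetherin, 0.194 and 248. Estrogen-induced genes were also lower, with 18 of 38 at least 2-fold lower, 4 higher and a median of -0.81 (percentile 0 among random lists). At the other end, IL8, the lactate dehydrogenase gene LDHB, the secretory gene MUCL1 and the MAP kinase feedback genes SPRY4 and DUSP6 were over 100-fold higher in TamR siControl than in parental siControl.

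Among the estrogen-induced genes, HSPB8 measured 0.182 RPKM in TamR and 286 in parental cells, CA12, a carbonic anhydrase, 0.206 and 151, and GREB1 2.27 and 41.8. CXCL12 had no read in TamR siControl and was at least 442-fold lower, against a floor of 3 reads. PGR, the progesterone receptor, was 5.28-fold lower (4.81 to 5.80). TFF3 went the other way, at 1107 against 31.0 RPKM, and TFF1 had a ratio of 1.14. ESR1 itself differed little, with a ratio of 1.02 (0.972 to 1.08). GATA3, a luminal transcription factor that acts with FOXA1, was 45.8-fold lower in TamR, while FOXA1 was 2.32-fold higher (2.24 to 2.41). IL8 was 1437-fold higher, with an interval of 491 to 6975 because the parental value rests on 3 reads. LDHB measured 274 against 0.391 RPKM, MUCL1 239 against 1.87, SPRY4 92.4 against 0.334, and DUSP6 120 against 0.857. In the profiles labelled siFOXA1, siER and siIL8, SPRY4 was lower than in TamR siControl, at 31.5, 51.9 and 25.8 RPKM, and so was DUSP6, at 32.8, 30.6 and 17.4.

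Growth factor receptors and ligands were higher in TamR in 7 of 17 measured members and lower in 1 (median 0.67, percentile 99.95). They included AREG, an EGFR ligand, at 1331 against 86.7 RPKM, HBEGF, BMP7 and EGFR, which was 12.2-fold higher (8.81 to 17.3). Cholesterol biosynthesis genes were higher in 11 of 23 members and lower in none, with a median of 0.94 (percentile 100) and MSMO1, STARD4, INSIG1 and LSS at 4.43-fold to 5.59-fold. In fatty acid synthesis 4 of 11 were higher and 1 lower (median 0.68), with the desaturase gene SCD 6.77-fold higher and FABP5 without a read in TamR. Unfolded protein response genes were higher in 8 of 19 (median 0.83), among them PDIA6 at 383 against 69.8 RPKM. Basal epithelial markers were higher in 6 of 16 and lower in 3 (median 0.59), with KRT81 20.2-fold higher and CD44 10.9-fold lower. Antigen presentation genes were lower in 5 of 11 (median -0.97), with B2M, the light chain of MHC class I, 8.44-fold lower, and DNA replication genes in 10 of 36 (median -0.57), with POLE2 6.67-fold lower. The growth factor, antigen presentation and DNA replication medians were not kept by every profile with a TamR label. Against parental siControl they were -0.12 (percentile 49.5), -0.42 (14.7) and -0.09 (62.0) for the profile labelled siFOXA1, and 0.13 (82.7), -0.41 (36.7) and -0.44 (7.58) for the TamR siIL8 profile. With TamR siER they were 0.39, -0.69 and -0.29. For the TamR siIL8 profile, the fatty acid synthesis and unfolded protein response medians, 0.56 (percentile 95.55) and 0.63 (95.36), also lay inside 95% of random lists. The serine synthesis gene PSAT1 had no read in TamR siControl and 60.2 RPKM in parental siControl.

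The interferon difference was not limited to the TamR siControl library. The median of the 37 interferon-stimulated genes was 40.9 RPKM in parental siControl, 19.3 and 9.21 in the libraries labelled without and with doxycycline, and between 0.494 and 0.990 in the 4 profiles with a TamR label. RMRP and RPPH1, structural RNAs of the RNase MRP and RNase P enzymes, had the largest log2 differences (pseudocount 1) among the higher genes, at 605 and 1291 RPKM in TamR siControl, while no other profile exceeded 2.30 and 4.03 RPKM. In all, 1129 genes were at least 2-fold higher and 1472 lower, and the median of all genes was -0.15. With that median set to 0, the split became 1396 higher and 1082 lower. With TamR siER in place of TamR siControl, a check chosen after the data were seen, 1253 were higher and 1578 lower, and 843 and 992 of the original genes were among them.

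**Figure D2:**
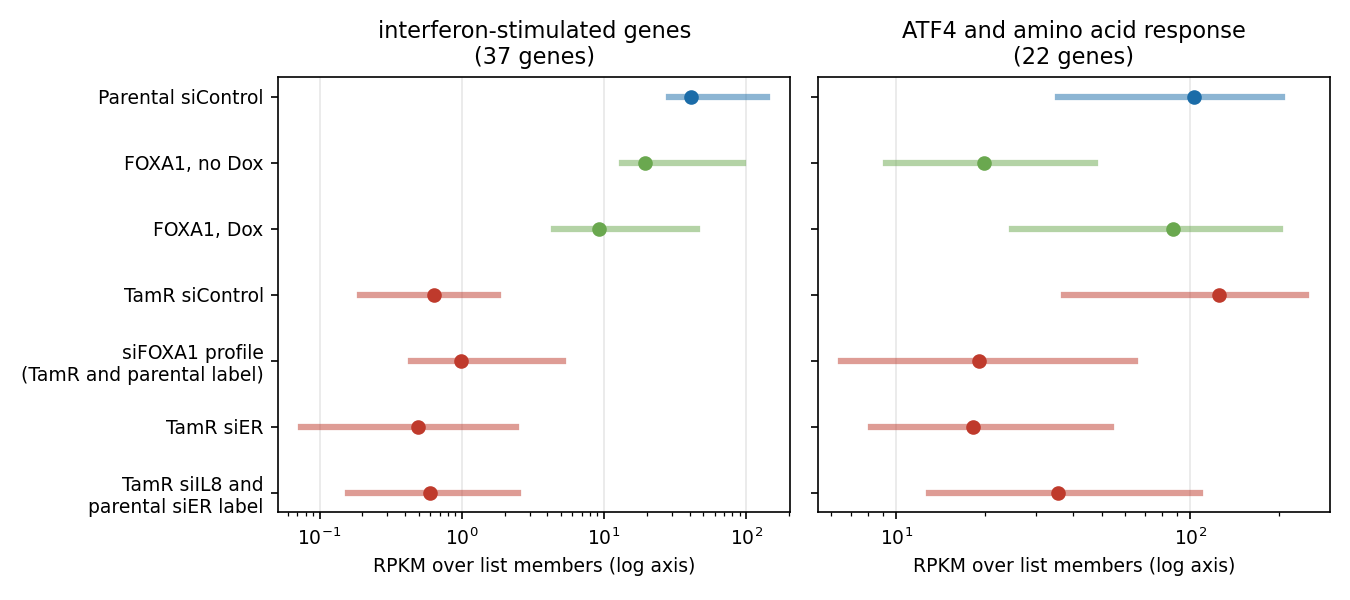
Median RPKM (point) and interquartile range (bar) over the members of 2 gene lists in the 7 distinct profiles, on log axes; colours mark the parental library (blue), the inducible pair (green) and profiles with a TamR label (red). Interferon-stimulated genes have medians under 1 RPKM in every profile with a TamR label, and ATF4 and amino acid response genes have medians of 125, 103 and 87.4 RPKM in TamR siControl, parental siControl and the library labelled with doxycycline.

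Loss of FOXA1 in TamR cells is the question named by the siFOXA1 label, but FOXA1 was not lower in that library, so the differences below describe the library labelled siFOXA1 and not a knock-down. Genes of the ATF4 and amino acid response, which cells raise when amino acids run short, were lower than in TamR siControl in 17 of 22 measured members and higher in none (median -2.04, percentile 0). CHAC1, which encodes a glutathione-degrading enzyme, measured 1.24 against 72.0 RPKM, NUPR1 5.57 against 154, ASNS, which makes asparagine, 15.9 against 195, and DDIT3 16.8 against 128. The largest log2 differences above TamR siControl (pseudocount 1) were those of DSCR8 at 57.1 against 1.20 RPKM, S100A8, a calprotectin subunit, at 59.0 against 1.39, and GPNMB at 12.2 against 0.0986. S100A7, which encodes psoriasin, had no read in TamR siControl and was at least 14.5-fold higher.

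Basal epithelial markers were at least 2-fold higher in 4 of 16 members and lower in 1 (median 0.56, percentile 100), with S100A2 and KRT16 7.04-fold and 5.0-fold higher and ID4 4.44-fold lower. Androgen-response and apocrine genes were higher in 3 of 11 and lower in 1 (median 0.60), with the apocrine marker PIP at 35.6 against 5.05 RPKM. AKR1B10, an aldo-keto reductase gene, was 11.2-fold higher and KYNU, of tryptophan breakdown, 8.54-fold higher. Mitosis genes had a median of -0.48, with 4 of 34 at least 2-fold lower, including NDC80, HMMR and TOP2A, while DNA replication genes had a median of 0.47, with CCNE1 3.02-fold higher. Estrogen-induced genes were at least 2-fold lower in 6 of 38 members and higher in 2 (median 0.11, percentile 89.8), and TFF1 was 1.87-fold lower (1.83 to 1.91) and PGR 1.84-fold higher (1.68 to 2.02). The 10 genes lowest by log2 difference were RPPH1, RMRP, CHAC1, NUPR1, IL8, the non-coding RNA BCYRN1, CLGN, the histone genes HIST1H4E and HIST1H1E, and EDN1, which encodes endothelin and was 15.4-fold lower.

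Of all genes, 239 were at least 2-fold higher and 333 lower in the library labelled siFOXA1. When TamR siIL8 took the place of TamR siControl these counts became 1043 and 180, with 65 and 18 of the original genes among them, the ATF4 list median moved from -2.04 to -0.66 and the mitosis median from -0.48 to 0.63. Against TamR siControl, TamR siIL8 itself had medians of 0.43 and -0.59 in the shortest and longest quintiles of gene-model length. The values under this replacement therefore also carry that library's own differences. The filter at a mean of 5 RPKM left 137 higher and 218 lower, and a pseudocount of 0.1 gave 465 higher.

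Knock-down of the estrogen receptor in TamR cells is the question of the siER label, although ESR1 was also lower in TamR siIL8. With ESR1 at a ratio of 0.61, estrogen-induced genes were lower in TamR siER in 11 of 38 members and higher in none (median -0.42, percentile 0). TFF3 measured 149 against 1107 RPKM, STC2 17.3 against 122, IGFBP4 73.2 against 265 and TFF1 726 against 1999, and GREB1 was 2.29-fold lower (1.91 to 2.74). The growth factor receptor genes EGFR and ERBB2 were 3.70-fold (3.24 to 4.24) and 1.90-fold (1.83 to 1.98) higher. ITGB6, an integrin subunit of epithelia, was 38.4-fold higher (26.5 to 57.8), at 40.8 against 1.06 RPKM.

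Other genes higher in TamR siER were CP, which encodes ceruloplasmin, at 79.1 against 9.89 RPKM, the fatty acid oxidation gene ACAA2 at 497 against 86.0, the lysine breakdown gene AASS at 32.3 against 4.86, SLC4A4, a bicarbonate transporter gene, at 6.28 against 0.284, and GPRC5A, 5.94-fold. GATA3 was 2.89-fold higher, at 21.6 RPKM. Targets of p53 had a median of -0.50 (percentile 0), with 5 of 23 at least 2-fold lower, among them GDF15 at 8.59 against 69.2 RPKM. MYC was 4.96-fold lower (4.75 to 5.18), and the list of MYC and ribosome biogenesis genes had a median of -0.49. As in the library labelled siFOXA1, ATF4 and amino acid response genes were lower in 18 of 22 members (median -1.74), with NUPR1 20.3-fold and PHGDH 7.63-fold lower, and mitosis genes in 9 of 34 (median -0.63). RMRP and RPPH1 were again at the low end.

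In TamR siER 253 genes were at least 2-fold higher and 385 lower. Against TamR siIL8 in place of TamR siControl the counts were 1572 and 673, with 110 and 55 of the original genes among them, and ESR1 was then higher by 0.27 on the log2 scale instead of lower by -0.69. The length trend of TamR siIL8 enters these values too, as ESR1 lies in the longest quintile. TamR siIL8 also carries the parental siER label, and its ESR1 value was below that of TamR siER, at 15.5 against 18.9 RPKM. As a control it is therefore not free of an siER label, and these values do not test the siER result. Under the replacement, the mitosis median became 0.50 and the ATF4 median -0.70. Estrogen-induced genes were also lower in TamR siIL8 than in TamR siControl (median -0.33, percentile 1.72). ERBB2 was also higher there, at 91.0 against 56.2 RPKM, while EGFR was lower, at 1.05 against 3.33. A pseudocount of 0.1 gave 468 higher genes and the filter at 5 RPKM gave 145.

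The effect of lowering IL8, which was high in TamR siControl, is the question of the siIL8 label. The same profile is deposited under the parental siER label, and IL8 was also low in the library labelled siFOXA1. The differences below therefore describe this profile and cannot be assigned to a lowering of IL8. Mitosis genes were lower in TamR siIL8 in 18 of 34 members and higher in none (median -1.05, percentile 0), with TOP2A at 11.2 against 77.7 RPKM, HMMR at 4.78 against 34.3 and the kinetochore motor CENPE at 1.74 against 11.4. ATF4 and amino acid response genes were lower in 13 of 22 (median -1.37, percentile 0), with the cystine transporter SLC7A11 8.37-fold lower (7.68 to 9.14). Growth factor receptors and ligands were lower in 7 of 17 and higher in 1 (median -0.61), including HBEGF, 10.7-fold lower, AREG, 3.06-fold lower, and ERBB3. The 10 genes lowest by log2 difference were RPPH1, RMRP, HIST1H4E, HIST1H1E, ZBED6, CLGN, IL8, HIST2H3A, HIST2H3C and CTGF, a matricellular protein gene that was 12.2-fold lower.

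Estrogen receptor cofactors and pioneer factors were lower in 8 of 19 members (median -0.95, percentile 0.01), with NCOA3 at 55.3 against 198 RPKM and EP300 4.44-fold lower. Cell adhesion genes were lower in 6 of 21 and higher in 1 (median -0.57), with DSP 3.35-fold lower. The genes highest by log2 difference were NUDT8 (7.0-fold), NACA2 (9.38-fold), C17orf89, GAS5-AS1, TMEM160 and the tubulin gene TUBB3, at 273 against 57.1 RPKM. Glycolysis and hypoxia response genes were higher in 4 of 25 and lower in 1 (median 0.47), with CA9 3.39-fold and PFKFB4 2.79-fold higher. ESR1 was 1.99-fold lower (1.89 to 2.10), and estrogen-induced genes were lower in 8 of 38 members and higher in none (median -0.33, percentile 1.72). The ESR1 value includes the shift of the longest quintile of genes, to which ESR1 belongs and whose median log2 difference was -0.59.

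Differences in this library followed gene-model length: the median log2 difference was 0.43 in the shortest quintile of genes and -0.59 in the longest, whereas in the library labelled siFOXA1 the same medians were 0.04 and 0.02. The quintile with a median length of 4252 nt had a median of -0.34. Median lengths were 4276 nt for cell adhesion genes, 4930 nt for growth factor receptors and ligands and 3757.5 nt for estrogen-induced genes. The random lists were matched on expression and not on length, so the percentiles of these lists do not account for this trend. Ribosomal protein genes held 24.1% of all RPKM, against 15.9% in TamR siControl. In total 790 genes were at least 2-fold higher and 1533 lower, and with the overall median of -0.12 set to 0 the split was 1083 and 1185. With the median of each length quintile set to 0, 984 were lower, the cofactor median moved from -0.95 to -0.36, and the mitosis and ATF4 medians were -0.99 and -1.43. Against TamR siER in place of TamR siControl, the ATF4 median became 0.70.

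**Figure D3:**
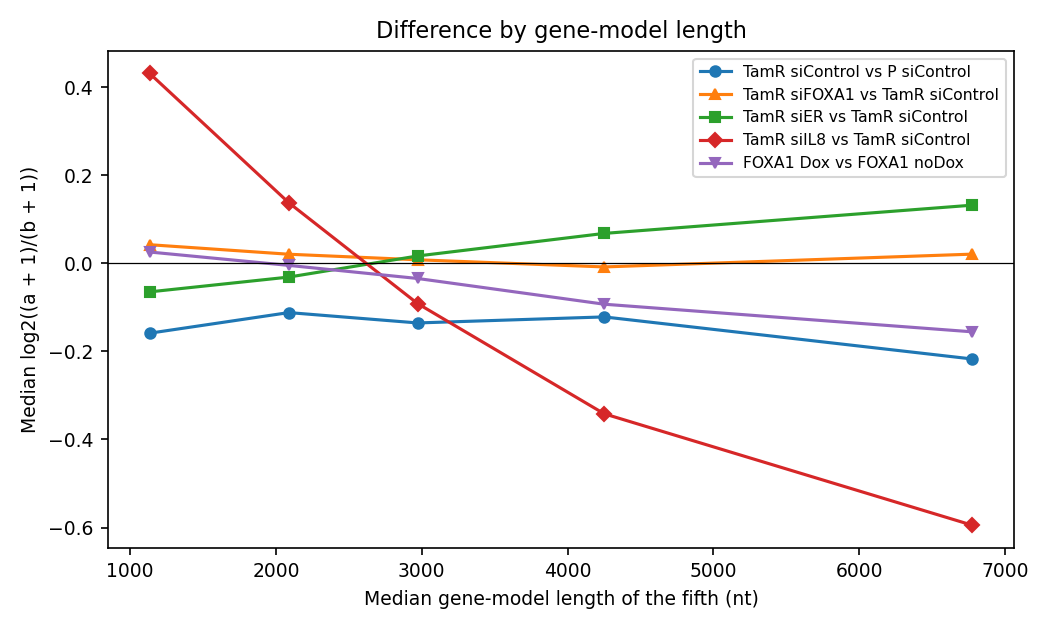
Median log2 difference of the genes in each quintile of gene-model length, plotted at the quintile's median length in nucleotides, for 5 comparisons (a against b as named in the key). In TamR siIL8 against TamR siControl the median goes from 0.43 in the shortest quintile to -0.59 in the longest.

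The parental siFOXA1 and siER labels would ask what both factors control in drug-sensitive cells, but each file repeats a profile that also carries a TamR label. Under the parental siFOXA1 label, interferon-stimulated genes were lower than in parental siControl in 35 of 37 members (median -4.25), LDHB was 669-fold higher, GATA3 21.1-fold lower and FOXA1 3.01-fold higher (2.93 to 3.09). Under the parental siER label the same list was lower in 35 of 37 (median -4.55), LDHB was 897-fold higher, GATA3 49.7-fold lower and ESR1 at a ratio of 0.513 (0.491 to 0.536). For the interferon-stimulated genes, LDHB and GATA3 these are the directions of the TamR siControl against parental siControl differences, while ESR1 differed little there. Across genes, r with that comparison was 0.86 for the siFOXA1 label and 0.74 for the siER label, where unchanged profiles simulated against the shared parental control gave 0.48 and 0.47.

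Under the parental siFOXA1 label, unfolded protein response genes were higher in 11 of 19 members (median 1.5) and basal markers in 10 of 16 (median 1.61), with MUCL1 177-fold higher and the calprotectin subunit gene S100A9 at 626 against 5.99 RPKM. Under the parental siER label, estrogen-induced genes were lower in 22 of 38 (median -1.51), with PGR 15-fold and GREB1 21.9-fold lower. TPM2, MUCL1 and BMP7 were 149-fold, 87.7-fold and 43.0-fold higher, and AGR2, which encodes a disulfide isomerase of the secretory pathway, was 41.6-fold higher. The counts were 1130 genes higher and 1453 lower for siFOXA1 (1386 and 1050 with the median of all genes, -0.14, set to 0, and 1337 and 1093 with upper-quartile scaling) and 1365 and 2853 for siER (1961 and 2092 with the median of -0.22 set to 0). With the median of each length quintile set to 0, the ESR1 log2 difference under the parental siER label moved from -0.92 to -0.13 and 1784 genes were lower.

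Induction of FOXA1 by doxycycline is the question of the inducible pair. FOXA1 was 6.44-fold lower in the library labelled with doxycycline, so each direction below is that of the labels as deposited. In the library labelled with doxycycline, estrogen-induced genes were higher in 21 of 38 members and lower in none (median 1.18, percentile 100), including CXCL12 at 42.9 against 2.94 RPKM, MYB 5.89-fold, PGR 5.03-fold (4.87 to 5.20) and GREB1 3.36-fold higher. ESR1 was 3.05-fold (2.91 to 3.19) and GATA3 2.89-fold higher. ATF4 and amino acid response genes were higher in 19 of 22 (median 1.83), with NUPR1 at 125 against 3.46 RPKM, PHGDH at 207 against 28.1 and TRIB3 at 147 against 21.9.

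Lower in the library labelled with doxycycline were FGB, which encodes fibrinogen beta, at 0.406 against 328 RPKM, the smooth muscle actin gene ACTG2 at 0.237 against 92.8, TARP at 3.79 against 131, the peripheral myelin gene PMP22 at 5.03 against 152, and ADM, which encodes adrenomedullin, at 0.145 against 27.5. KHDC1L and the protease gene MMP10 had no reads there and were at least 1592-fold and 288-fold lower. Mesenchymal markers were lower in 3 of 8 members (median -0.94), with fibronectin, FN1, 42.5-fold and TGFBR2 5.89-fold lower. Interferon-stimulated genes were lower in 19 of 37 (median -1.10), with IFIT1 at 25.4 against 95.7 RPKM, and antigen presentation genes in 4 of 11 (median -0.85), with HLA-B 3.42-fold lower. Luminal genes were higher in 12 of 29 and lower in 2 (median 0.65), the 2 lower members being FOXA1 and AGR2, and KRT19 was 3.19-fold higher. Cholesterol biosynthesis genes had a median of -0.44, with DHCR24 3.71-fold lower. In total 392 genes were at least 2-fold higher and 688 lower, and the filter at 5 RPKM left 430 lower.

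**Figure D4:**
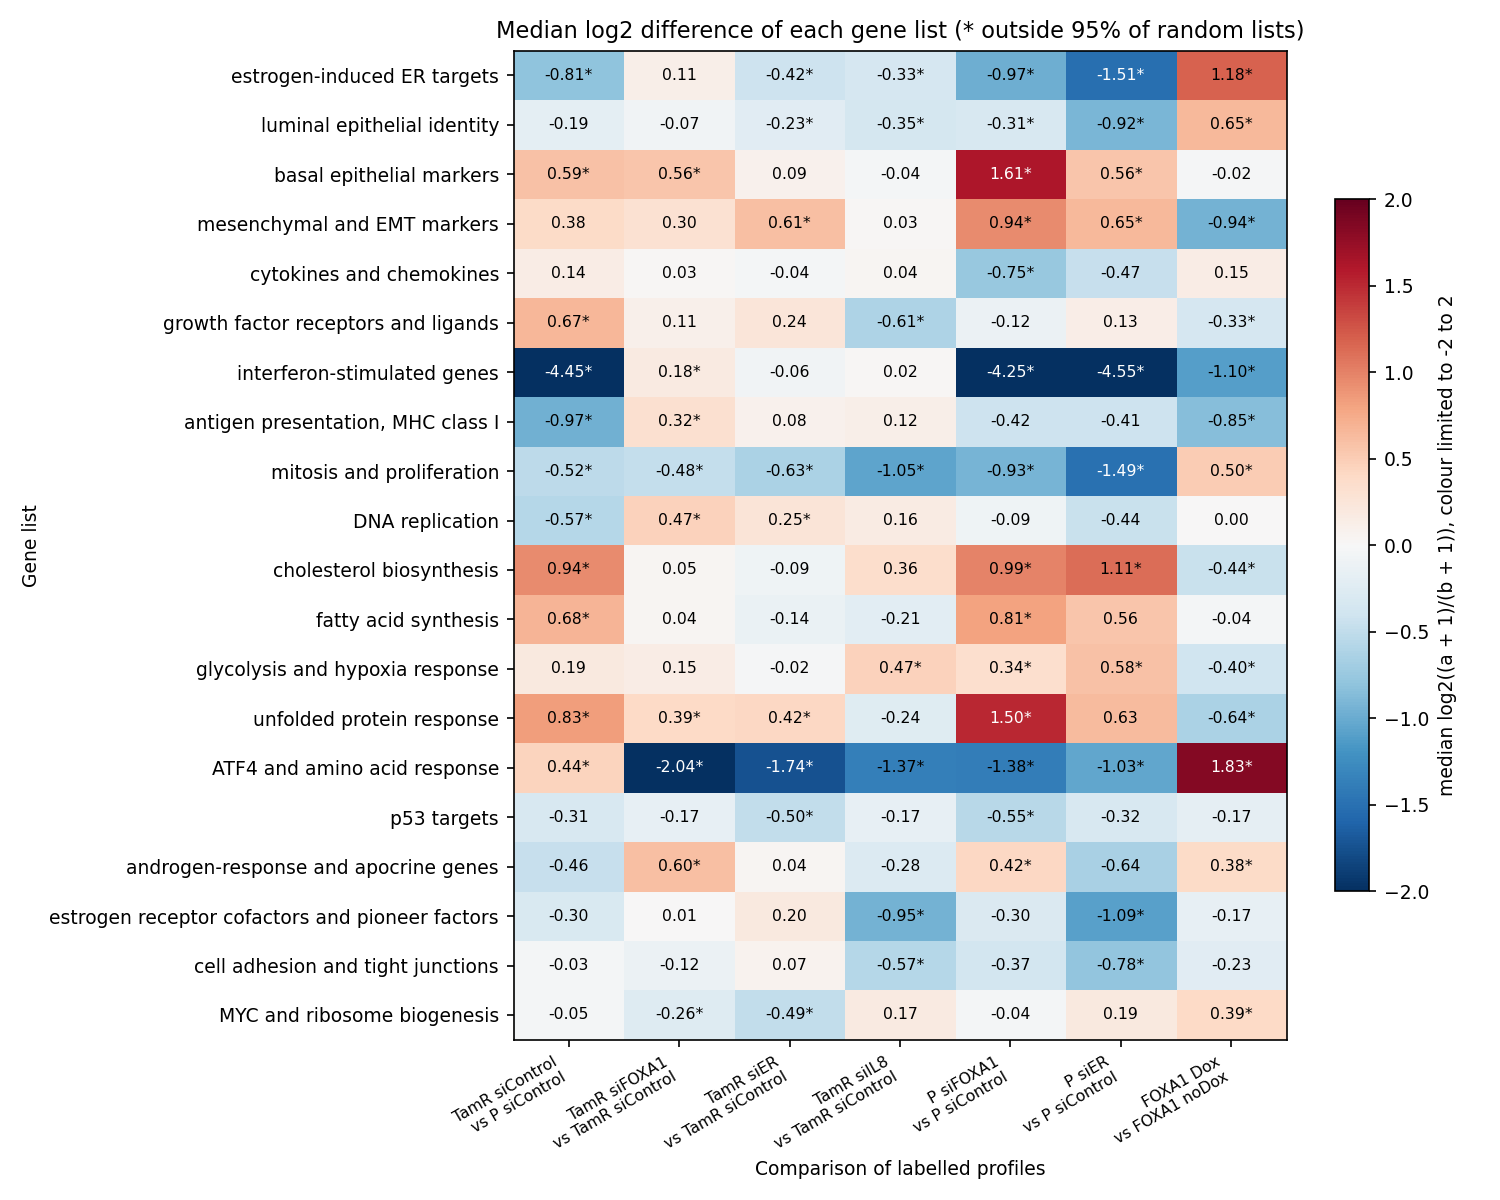
Median log2 difference of each gene list (rows) in the 7 labelled comparisons (columns), with red for higher and blue for lower in the first-named profile and an asterisk where the median lies outside 95% of 10000 expression-matched random lists. ATF4 and amino acid response genes have medians of -2.04, -1.74 and -1.37 in the 3 TamR comparisons with TamR siControl and 1.83 in the inducible pair as labelled.

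Responses were then compared across genes, which are not independent replicates. The differences of the library labelled siFOXA1 and of TamR siER from TamR siControl correlated with r = 0.76 (rho 0.72), against 0.61 for simulated unchanged profiles with a shared control, and their covariance was 0.216 against 0.0304 simulated. Of the genes, 238 were lower in both, among them CHAC1, NUPR1 and RMRP. Independent lists would share 10.3, a value that ignores the shared control. With TamR siIL8 as the control of the siER response, r was -0.0861, but that profile also carries the parental siER label. The responses labelled siFOXA1 and siIL8 gave r = 0.61 against 0.61 simulated, with a covariance of 0.249 against 0.0300, and those of TamR siER and TamR siIL8 gave r = 0.43 (rho 0.30) against 0.60 simulated, with a covariance of 0.180 against 0.0302. All 3 pairs share the TamR siControl library, so no r or overlap among them can be read apart from it.

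Across all 3 TamR comparisons, 196 genes were at least 2-fold lower than in TamR siControl and 62 higher, against 1.7 and 12.3 in simulated unchanged profiles and 1.26 and 0.307 for independent lists. The simulated values rest on the assumed dispersion of 0.01 and do not cover larger variation between cultures or libraries. The TamR minus parental difference and the response labelled siFOXA1 in TamR, which contain TamR siControl with opposite signs, gave r = -0.33 against -0.59 simulated, with a covariance of -0.174 against -0.0297. The inducible pair, as labelled, correlated with the TamR minus parental difference at r = -0.23, with the TamR response labelled siFOXA1 at -0.08 and with the parental response labelled siFOXA1 at -0.28, with no shared library in any of these. The siFOXA1 responses under the TamR and parental labels gave r = 0.20, a value without meaning for the cells because both contain 1 and the same profile, and those labelled siER gave 0.10. The siFOXA1 and siER responses under parental labels gave 0.84 against 0.53 simulated. Both of these profiles also carry TamR labels, and against parental siControl they gave r of 0.86 and 0.74 with the TamR minus parental difference. Neither 0.84 nor the 0.10 of the siER labels can therefore be read as a response of parental cells.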

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

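All tests in this part were chosen after the results were seen. The same siRNA label gave differences of at least 2-fold in opposite directions under the TamR and parental labels for 2 of the genes fixed by name, and the difference between the cell lines was not tested. IL8 differed from siControl by -4.41 on the log2 scale under the TamR siFOXA1 label and by 2.22 under the parental one, and by -1.95 and 3.01 under the siER labels. GATA3 differed by 1.02 and -4.32 under the siFOXA1 labels and by 1.41 and -5.44 under the siER labels.

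For siFOXA1, both labels hold 1 and the same profile. For siER they do not: the parental file repeats TamR siIL8, and it shared 3 identical values above 0 with TamR siER. The controls themselves differed, with IL8 at 105 RPKM in TamR siControl and 0.0733 in parental siControl, and GATA3 at 7.46 and 342. Under the explanation that 1 profile was deposited under both siFOXA1 labels, all values above 0 should be identical, and 17970 of 17970 were; for TamR siIL8 and parental siER it was 17034 of 17034, against at most 67 in any other pair. That the shared profiles came from parental cells is argued against by their median positions between parental (0) and TamR siControl (1), 0.94 for siFOXA1 (lower quartile 0.76) and 0.95 for siIL8 and siER (lower quartile 0.71). On these values the profiles resemble TamR cells, and a file placed under a wrong parental label is a candidate explanation. They do not settle whether the profile labelled siIL8 and siER came from an siIL8 or an siER transfection. The deposited file under the parental siFOXA1 label also carries TR in its name, as does the file under the TamR siFOXA1 label. No biological explanation was tested.

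FOXA1 in the inducible pair went against both labels. Leaky expression without doxycycline and no other fault would leave FOXA1 at least as high with doxycycline, but the ratio was 0.155, with an upper counting bound of 0.159. Exchanged labels may account for it: FOXA1 was 8.98-fold above parental siControl in the library labelled without doxycycline and 1.39-fold above it in the other. The library labelled with doxycycline was also nearer to parental siControl over all genes (r 0.977 against 0.925 for the other), which an exchange of labels allows. A lowering of FOXA1 by doxycycline alone would need another reason for the 8.98-fold level without it; together with leaky expression it stays open, untested.

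For 196 genes TamR siControl, the control of every TamR comparison, was at least 2-fold above the other 3 TamR profiles, although over all genes TamR siIL8 lay further from the siFOXA1 and siER labels (r 0.953 and 0.932, against 0.960 and 0.957 for TamR siControl). That RNAs without a poly(A) tail were kept in that library alone stays open for histone genes: 35 of 50 were at least 2-fold above the other 3 TamR profiles but 16 above all 6 others, with medians of 11.4 RPKM there and 10.5 in parental siControl, from the line that TamR was derived from. It also stays open for RMRP and RPPH1, 263-fold and 320-fold above their highest values elsewhere but chosen for the pattern. For ATF4 and amino acid response genes, it would leave the median high in TamR siControl only. That median was 103 RPKM in parental siControl and at most 35.5 in the other 3 TamR profiles. RMRP and RPPH1 were 1.24 and 4.03 RPKM in parental siControl. The inducible pair, labelled without and with doxycycline, had ATF4 medians of 19.9 and 87.4 but histone medians of 7.25 and 7.99. These values argue against it for the ATF4 list. They come from libraries of other cells than TamR, and histone genes were also high in parental siControl. Counting error of the shallow library is argued against for the ATF4 list, as 20 of its 22 members had counting intervals below a ratio of 1 in all 3 comparisons. A response of these genes to each siRNA, or a difference in culture state at harvest, stays open and was not tested.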

How the results depend on the processing

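No paired analysis was possible because each group had 1 profile and no replicate numbers link the groups. Over 108 results and 780 alternative values, 726 stayed within the limits given for the processing, 50 moved and 4 reversed. List medians, and IL8 differences other than that of the siIL8 label, also depended on the treatment of low values. Of these, 8 moved without a filter and 4 with the filter at 5 RPKM. With pseudocounts of 0.1 and 0.5, 7 and 2 moved. A list median was counted as reversed only where it started at 0.58 or more from 0. These limits are wide: a smaller list median could reach 0 and still count as unchanged. The TamR against parental siControl counts also stayed within 1.5-fold when 1129 higher and 1472 lower became 1396 and 1082, which changed the majority direction. Of those that moved, the mitosis median of the library labelled siFOXA1 also changed sign, to 0.63 with TamR siIL8 as control, and so did the ATF4 median of TamR against parental siControl, from 0.44 to -1.29 with TamR siER. The TamR siER replacement, the length setting and every replacement for list medians were chosen after seeing the data. The cause was not tested for any of the values below unless the alternative itself gives it. With TamR siIL8 in place of TamR siControl, the library labelled siFOXA1 had 1043 genes higher and 180 lower, TamR siER had 1572 and 673, ESR1 in TamR siER reversed to 0.27, and the mitosis median in TamR siER reversed to 0.50; the correlation of the siFOXA1 and siER responses reversed to -0.0861 with that control for siER. As TamR siIL8 also carries the parental siER label, its use as a control does not test the siER values. With TamR siER as the control, the ATF4 median of TamR siIL8 reversed to 0.70. A pseudocount of 0.1 raised the higher genes to 465 (siFOXA1 label) and 468 (siER). The filter at 5 RPKM, which tests fewer genes, left 137 higher and 218 lower (siFOXA1 label), 145 higher (siER) and 430 lower (inducible pair). Upper-quartile scaling, the median set to 0 and the length-quintile medians set to 0 moved FOXA1 under the parental siFOXA1 label to 1.72, 1.72 and 1.72, FOXA1 in TamR against parental siControl to 1.32, 1.36 and 1.34, and ESR1 under the parental siER label to -0.80, -0.69 and -0.13. The first 2 of these moved FOXA1 in the inducible pair to -2.61 and -2.62. The length-quintile setting moved ESR1 in TamR siER to -0.82 and the lower genes to 984 (siIL8) and 1784 (parental siER label). Every other correlation stayed within 0.1 under the pseudocounts, filters and upper-quartile scaling. Depth limits TamR siControl, where 3 reads in a gene of 1 kilobase correspond to 0.273 RPKM, against 0.0476 RPKM in the library labelled siFOXA1.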

Other observations

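All comparisons in this part were chosen after the results were seen. MYC was measured beside the ATF4 and amino acid response genes. It was 196 RPKM in TamR siControl, 173 in parental siControl and 140 in the library labelled with doxycycline, against 73.9 in the library labelled siFOXA1, 39.6 in TamR siER, 121 in TamR siIL8 and 26.7 in the library labelled without doxycycline. SHMT2, a mitochondrial serine pathway enzyme, measured 247, 115, 111, 80.4, 76.5, 128 and 42.1 RPKM in the same order. TOP2A, which peaks late in the cell cycle, went from 77.7 RPKM in TamR siControl to 30.9, 29.9 and 11.2 in the profiles labelled siFOXA1, siER and siIL8, while PCNA, a replication factor, went from 82.5 to 149, 128 and 148. MYC, SHMT2, TOP2A and PCNA were chosen here after their values were seen.

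Several genes that differed between TamR and parental siControl lay apart from parental siControl in every profile with a TamR label. LDHB lay between 204 and 350 RPKM in the 4 profiles with a TamR label and had 14 reads in parental siControl (0.391 RPKM) and none in the inducible pair. PSAT1, of the same serine pathway as PHGDH, had 0, 4, 0 and 2 reads in TamR siControl, the library labelled siFOXA1, TamR siER and TamR siIL8, and 60.2 RPKM in parental siControl. BMP7 measured 311 RPKM in TamR siControl and 849 in TamR siER, against 15.5 in parental siControl.

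Some genes that differed between TamR and parental siControl also differed in the inducible pair. Genes higher in TamR and in the library labelled without doxycycline numbered 203, where independent lists share 62.2, and genes lower in both numbered 161, where independent lists share 46.2. AGR2, FN1 and BMP7 were higher on both sides, with BMP7 at 147 RPKM in the library labelled without doxycycline and 25.9 in the other, and GATA3 and GREB1 were lower. Interferon-stimulated genes went in opposite directions, being higher in the library labelled without doxycycline (19.3 against 9.21 RPKM) and lower in TamR.

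The length trend of the profile labelled TamR siIL8 and parental siER, with medians of 0.43 and -0.59 in the shortest and longest quintiles, is given as a value only.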
